A study of Mus musculus with 12 samples.

How the data were processed

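Gonadal white adipose tissue was taken from male C57BL/6 mice, either wild type (WT) or lacking the microRNA gene Mir10a (KO, for miR-10a knockout). The mice ate a normal chow diet (NCD) or a high-fat diet (HFD) for 16 weeks from the age of 8 weeks, per the labels' protocols. Polyadenylated RNA was sequenced as 12 libraries, 3 biological replicates in each of 4 groups. RNA was taken up in TRIzol and libraries were made with the TruSeq Stranded mRNA LT kit, per the labels' protocols.

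The deposited table gives FPKM, a fragment count scaled by transcript length and library size, for each gene and library, per the file headers. It lists 30268 genes by NCBI gene ID. The submitters' processing notes name bcl2fastq 2.20.0, Trimmomatic, HISAT2 2.1.0, StringTie 1.3.4d and the genome build mm10, and per the submitters' processing notes DESeq2 was used as well, without the role of each program for this table being stated. The table holds no counts, so the depth of each library is unknown and no counting error can be given. FPKM is a relative scale within each library, so a rise of a few abundant transcripts lowers all others.

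All 12 value columns were used. Each column was assigned to a group by the genotype and diet in its header. The animal numbers in the headers differ from the replicate numbers in the sample titles, so a column was tied to a group and not to a single titled sample. Libraries are named here by group and the number in the header, such as KO_HFD 8. Of the gene IDs, 30196 were matched to symbols and positions in the mouse reference annotation for GRCm38.p6, the assembly called mm10. The other 72 IDs were kept in the tests without a name, and 24 of them were tested.

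A count-based test (edgeR) had been planned, with limma set as the fallback for a table without counts, and the fallback was used because the file holds FPKM. Values were transformed as log2(FPKM + 1). A gene was tested if it reached 1 FPKM in at least 3 of the 12 libraries, which kept 14340 genes. A linear model with 4 group means and 8 residual degrees of freedom was fitted with limma 3.58.1 in R 4.3.3, using empirical Bayes moderation with a mean-variance trend. All 12 libraries shared a single estimate of the spread per gene. P-values were adjusted by the Benjamini-Hochberg (BH) method within each comparison, with a threshold of 0.05. Adding 1 FPKM before taking logs shrinks the fold changes of genes below a few FPKM, so log2 fold changes of low genes understate the ratio of their FPKM values. The 5 comparisons were the diet effect in WT, the diet effect in KO, the genotype effect on NCD, the genotype effect on HFD, and the difference of the diet effects between genotypes (the interaction).

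Before the data were examined, 35 lists of genes were fixed from general knowledge of fat tissue. They cover immune, stromal and parenchymal cell types, tissues next to the fat pad, lipid and energy metabolism, and signalling responses. The 33 lists with at least 3 tested members were tested with camera in limma, which asks whether the members of a list changed more in one direction than the other tested genes. A preset correlation of 0.01 between members was used, with BH adjustment over the lists of a comparison. Members of such lists rise and fall together between animals, so the preset correlation gives p-values that are too small where members are coupled, and camera was also run with a correlation estimated for each list. The fry test was run as well, which asks whether members move on balance in one direction without reference to other genes. The design, the alternatives and the rule for naming genes were also fixed before the data were examined.

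The rule for naming genes took the 5 highest and 5 lowest log2 fold changes past the threshold, with a mean of at least 1 FPKM and no overlap between the 2 groups. For these 10 it passed over unnamed predicted genes and pseudogenes. It added up to 4 members from each of the 10 lists with the lowest camera p, taking the lowest p-values among members past the threshold, or the 2 most abundant members where fewer than 2 passed. It always included Lep, Adipoq, Adgre1, Ccl2, Trem2, Col1a1, Fasn, Ucp1, Map3k7, Klf11, Hoxb3 and Hoxb4. Other genes are said to have been chosen after their values were seen. A few genes that the rule picked are not reported here.

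Sites for the seed of miR-10a-5p were searched in the longest annotated 3' untranslated region (3' UTR) of each gene in GENCODE release M21. A 3' UTR was found for 12482 of the 12747 tested protein-coding genes, which is 97.9%. Genes with an 8mer or 7mer-m8 site were compared with genes without one by camera, and their median change was set against that of 100 control 7-base sequences of the same base composition. Positions of genes that differed between genotypes were compared with the window of 25 Mb on each side of Mir10a by Fisher's exact test.

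The scripts were tested on simulated data before use, with values drawn for the 14340 real genes and 200 genes changed by known amounts. For KO against WT on HFD, 82% of genes with a simulated log2 change of 1 were called, and 46% of those with a change of 0.5. For the diet effect in KO these shares were 80% and 40%. For the interaction they were 70% and 16%. There were 9 false calls in each of these 3 comparisons, which were read from the same simulated values, and none among unchanged groups. Errors were drawn independently for each gene, so the false calls do not cover correlation between genes. Alternatives tried were quantile normalization, limma without the trend, other filters on low values, a pseudocount of 0.1, fits with only the 2 groups compared, a fold-change threshold, and leaving out each library in turn. Median centring of each library, leaving out 3 libraries with ciliated-epithelium transcripts, and leaving out genes near Mir10a were added after the data were seen. No library was left out of the main comparisons.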

Results

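Expression of genes in gonadal fat was measured as FPKM in 12 mRNA-seq libraries, 3 each from WT mice on NCD, KO mice on NCD, WT mice on HFD and KO mice on HFD. The depth of each library is unknown, because the table holds FPKM and no counts. The sum of FPKM over all genes ranged from 383633 to 455434, and 12859 to 13667 genes reached 1 FPKM in a library. Mitochondrially encoded transcripts made up 7.52% to 17.5% of the summed FPKM, with the lowest share in KO_HFD 8 and the highest in KO_NCD 4. The first principal component of the tested genes held 75.9% of the variance and separated the diets, with NCD libraries from -54.9 to -35.7 and HFD libraries from 28.3 to 68.7. The second component held 6.85% and set WT_NCD 2, WT_NCD 4 and KO_NCD 2, at 11.6 to 27.8, apart from the other 3 NCD libraries, at -20.3 to -18.1. Those 3 libraries carried transcripts of ciliated epithelium, so counts of genes are also given without them where they moved. Values are mean FPKM ± SD with n = 3 per group, and log2 fold changes are differences of log2(FPKM + 1) from limma with BH adjustment.

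The targeted gene, Mir10a (NCBI gene 723893, mm10 chromosome 11, 96317165 to 96317274), was listed between 0.022 and 0.425 FPKM in every library. In the WT libraries it was listed at 0.425, 0.061 and 0.265 FPKM on NCD and 0.199, 0.022 and 0.102 on HFD. In the KO libraries it was listed at 0.276, 0.081 and 0.133 on NCD and 0.183, 0.268 and 0.153 on HFD. These values check nothing about the genotype labels, since libraries of polyadenylated mRNA do not measure a mature microRNA. Mir10a lies in the HoxB cluster of developmental transcription factors, inside the annotated span of Hoxb3 (NCBI gene 15410, 96307101 to 96347930) and next to Hoxb4 (15412, 96318267 to 96321638). Hoxb3 was at 3.41 ± 0.803 in WT and 3.16 ± 1.03 in KO on NCD, and Hoxb4 at 4.33 ± 0.727 and 5.23 ± 1.18. On HFD, Hoxb3 was at 2.09 ± 0.301 and 1.92 ± 0.636, and Hoxb4 at 2.86 ± 0.240 and 2.93 ± 0.637, and no genotype difference passed the threshold (adjusted p 0.815 to 0.986 over these 4 tests).

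The comparison of HFD with NCD in WT mice asked what 16 weeks of high-fat feeding changed in normal fat. The highest log2 fold changes included genes of lipid-laden macrophages. Mmp12 (NCBI gene 17381, a macrophage elastase) went from 1.70 ± 0.516 to 165 ± 53.5 FPKM (log2 fold change 5.91, SE 0.40, adjusted p = 1.72e-06). Gpnmb (93695, a lysosomal glycoprotein) went from 5.30 ± 1.12 to 361 ± 154 (5.78). Atp6v0d2 (242341, a subunit of the lysosomal proton pump) rose by 5.76 and Ubd (24108, an inflammation-induced ubiquitin-like protein) by 5.60. Tph2 (216343), which encodes the neuronal form of the enzyme that starts serotonin synthesis, rose from 0.203 ± 0.0378 to 48.5 ± 3.48 (5.36). The lowest log2 fold changes included genes of working adipocytes. Cfd (11537, the adipokine adipsin) went from 6816 ± 579.7 to 309 ± 138 FPKM (-4.56, SE 0.49, adjusted p = 3.27e-05). Cyp2e1 (13106, a cytochrome P450) went from 1830.4 ± 358 to 84.6 ± 36.2 (-4.51) and Adrb3 (11556, the adrenergic receptor that starts lipolysis) from 382 ± 11.1 to 23.4 ± 7.32 (-4.02). Fam13a (58909), linked to adipocyte insulin signalling, fell by 3.81 and Adgrg2 (237175, an adhesion receptor also found in efferent ducts) had -3.43.

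Macrophage genes rose as a group. Of 16 tested macrophage markers 15 rose and 1 fell (median 2.23, camera adjusted p = 6.82e-10, adjusted p = 0.317 with an estimated correlation). They included Adgre1 (encoding F4/80, from 9.03 ± 2.03 to 105 ± 19.5 FPKM), Cd68 (3.87), Fcgr1 (2.38), C1qb (2.17) and Tyrobp (3.07). Of 16 markers of lipid-associated macrophages, the cells that take up lipid from dying adipocytes, 15 rose (median 3.25, camera adjusted p = 1.57e-10, adjusted p = 0.317 with an estimated correlation). They included Trem2 (a lipid receptor, from 3.94 ± 0.0616 to 124 ± 25.4), Itgax (encoding CD11c, from 1.49 ± 0.188 to 57.7 ± 9.22) and the lysosomal protease gene Ctsk (from 9.86 ± 0.867 to 117 ± 4.70). Of 19 genes for inflammatory cytokines and receptors 18 rose (median 1.44, camera adjusted p = 2.03e-09, adjusted p = 0.317 with an estimated correlation). Among them were the chemokine genes Ccl2 (3.05) and Ccl3 (1.88), Tlr2 (1.33) and Tnfrsf1b (1.97). Antigen presentation genes rose as well, 11 of 14 higher and 3 lower (median 0.86, camera adjusted p = 0.00120, adjusted p = 0.455 with an estimated correlation). The MHC class II genes H2-Aa (1.46) and H2-Eb1 (1.38) and their regulator Ciita (1.68) were among them. All 20 tested cell cycle genes rose (median 1.72, camera adjusted p = 4.14e-12, adjusted p = 0.323 with an estimated correlation). The mitotic genes Cdk1 (1.70), Ccnb2 (1.98), Aurkb (1.58) and Birc5 (2.31) belong to this list.

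Matrix genes rose with the immune genes. Of 26 matrix and fibrosis genes 24 rose and 1 fell (median 1.27, camera adjusted p = 6.55e-10, adjusted p = 0.317 with an estimated correlation). Col6a3, which encodes a collagen of the adipocyte pericellular matrix, rose from 13.2 ± 2.37 to 71.1 ± 8.73 FPKM. The fibrillar collagen gene Col1a1 rose by 1.91, the collagen cross-linking enzyme gene Lox by 1.78, and the matrix protease genes Mmp2 and Mmp14 by 1.91 and 1.3. Cholesterol synthesis genes rose, 17 of 20 higher and 1 lower (median 0.83, camera adjusted p = 6.95e-06, adjusted p = 0.317 with an estimated correlation), for example Hmgcs1 (1.84) and Dhcr7 (2.03). The satiety hormone gene Lep, which adipocytes make as they enlarge, rose from 279 ± 93.4 to 1003 ± 160.1 (1.88, adjusted p = 0.000536). Of 12 obesity-raised adipocyte genes 7 rose and 1 fell (median 0.84, camera adjusted p = 0.0339, adjusted p = 0.498 with an estimated correlation). Interferon response genes rose with 8 of 19 higher (median 0.29, camera adjusted p = 0.0339, adjusted p = 0.670 with an estimated correlation). Without the 3 ciliated NCD libraries the last 2 list calls were lost, with adjusted p = 0.0628 and 0.159.

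Metabolic genes of adipocytes fell. Of 20 genes of adipocyte identity and insulin response 17 fell and none rose (median -1.13, camera adjusted p = 6.01e-07, adjusted p = 0.455 with an estimated correlation). Among them were the adiponectin gene Adipoq (from 2071 ± 193 to 988 ± 147), Irs1 (an insulin receptor substrate, -1.34) and Acvr1c (an activin receptor, -1.29). Of 18 genes that break down branched-chain amino acids 16 fell (median -0.93, camera adjusted p = 1.55e-06, adjusted p = 0.455 with an estimated correlation). They included Bcat2, which takes the first step (-1.34), Dbt (-1.03), Ivd (-1.48) and Aldh6a1 (-1.48). Of 24 genes of oxidative phosphorylation 18 fell (median -0.38, camera adjusted p = 4.15e-05, adjusted p = 0.572 with an estimated correlation), such as Ndufb8 (-0.94), Ndufs3 (-0.60) and Uqcrc2 (-0.55). Lipogenesis genes went down with 10 of 17 lower and 1 higher (median -0.62, camera adjusted p = 0.00707, adjusted p = 0.455 with an estimated correlation), including Fasn, the fatty acid synthase gene (-1.11). Mesothelial markers fell in 11 of 12 (median -1.37, camera adjusted p = 0.00182, adjusted p = 0.572 with an estimated correlation). Smooth muscle markers fell in 7 of 10, with 1 higher (median -1.04, camera adjusted p = 0.0221, adjusted p = 0.572 with an estimated correlation). Klf11, a transcription factor gene, fell by 0.53 (adjusted p = 0.00549), while Map3k7, which encodes the kinase TAK1, showed no change past the threshold (0.08, adjusted p = 0.464). Both have been named as targets of miR-10a. Ucp1, the heat-producing uncoupling protein gene of brown and beige fat, was not tested, as it reached 1 FPKM in only 2 libraries, with a highest value of 1.94.

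In all, 7279 of 14340 genes (50.8%) changed with diet in WT, 3645 higher and 3634 lower, and 1617 of them by at least 1 on the log2 scale. Leaving out single libraries gave 5849 to 7166 genes, and leaving out the 3 ciliated NCD libraries gave 3878. Of 55 named genes past the threshold, 54 stayed past it in every such fit, and Hoxb4 (-0.46, adjusted p = 0.0330) did not without WT_NCD 2, WT_NCD 4, WT_HFD 1 or WT_HFD 4. Without the 3 ciliated libraries, which leaves 1 WT library on NCD, Adipoq, Klf11 and Hoxb4 lost their calls (adjusted p = 0.0548, 0.0978 and 0.370). Hoxb3 (-0.50, adjusted p = 0.0683) passed it only without WT_NCD 1. Of 33 lists, 16 were called with the preset correlation (9 higher, 7 lower), none with an estimated correlation, and 22 with fry, which asks if members move on balance one way.

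**Figure D1:**
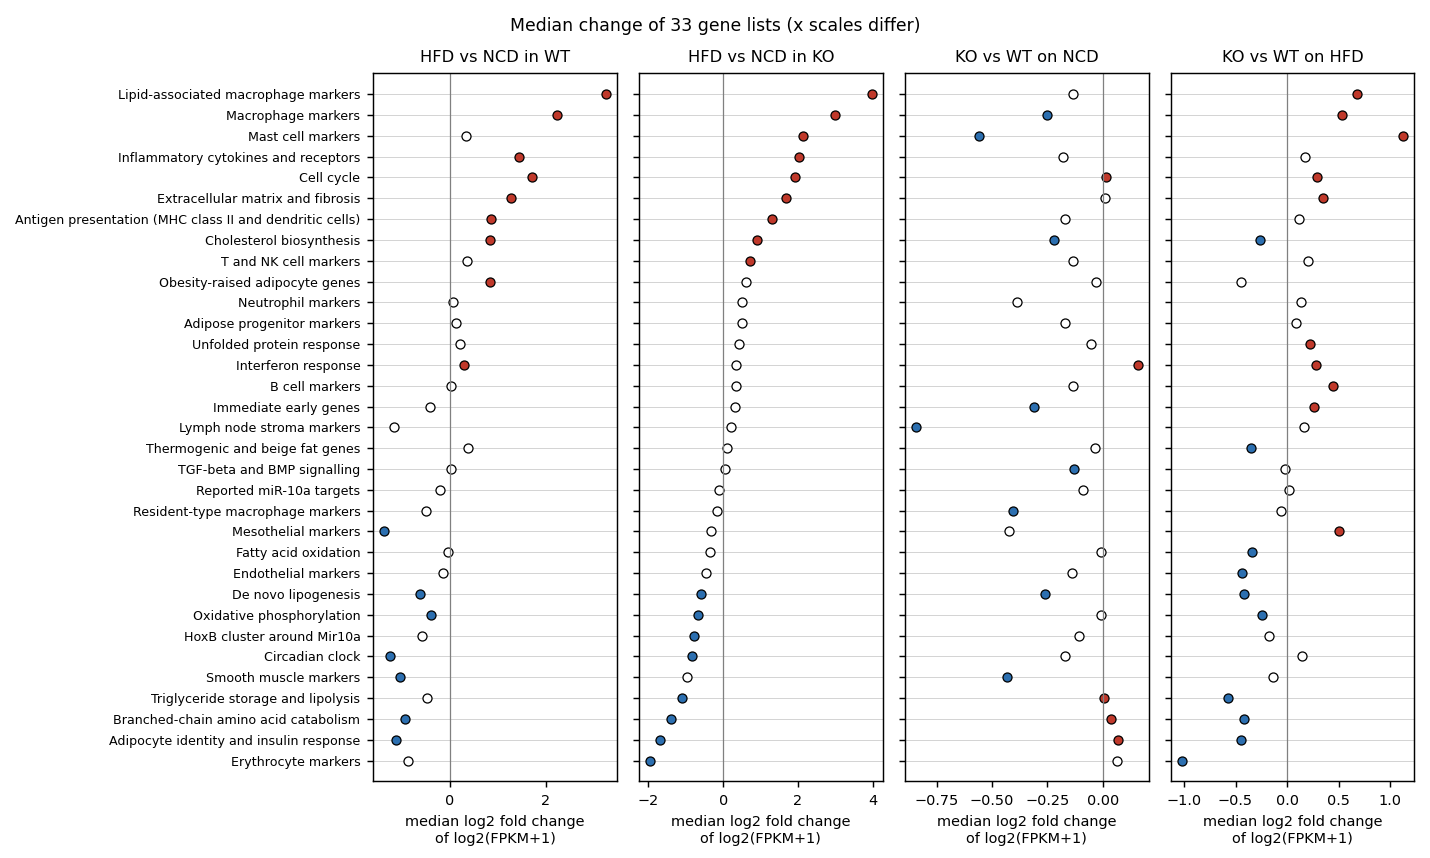
Median log2 fold change of log2(FPKM + 1) of each of 33 gene lists in 4 comparisons, on horizontal axes that differ in scale. Filled points mark lists with a camera adjusted p under 0.05 at the preset correlation, red for higher and blue for lower, and with an estimated correlation no list passed. The lipid-associated macrophage list lies at 3.25 for the diet effect in WT and 3.97 in KO, and the mast cell list at 1.13 for KO against WT on HFD.

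The comparison of HFD with NCD in KO mice asked the same question without miR-10a. Mmp12, Gpnmb and Atp6v0d2 had the 3 highest log2 fold changes named, as in WT. Mmp12 went from 1.41 ± 0.930 to 396 ± 229 FPKM (7.29, SE 0.40, adjusted p = 1.72e-07). Gpnmb went from 3.64 ± 0.578 to 724 ± 283 (7.23), and Atp6v0d2 and Trem2 rose by 6.71 and 5.74. Rgs1 (50778), a brake on chemokine receptor signalling in leukocytes, rose by 5.63. Cyp2e1 fell from 1867 ± 1079 to 17.3 ± 6.92 (-6.61) and Cfd from 7683 ± 3459.7 to 141 ± 94.0 (-5.90, adjusted p = 2.79e-06), followed by Adrb3 (-4.88), Fam13a (-4.59) and Retn (57264, the adipokine resistin, -4.05). Lep rose from 274 ± 99.0 to 773 ± 226 and Adipoq fell from 2217 ± 306 to 604 ± 208 FPKM. Col1a1 rose by 2.57, Ccl2 by 3.37 and Adgre1 by 4.43, while Fasn fell by 1.23.

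Macrophage markers rose in 15 of 16, with 1 lower (median 3.0, camera adjusted p = 1.88e-08, adjusted p = 0.405 with an estimated correlation). Lipid-associated macrophage markers rose in 15 of 16, with 1 lower (median 3.97, camera adjusted p = 2.25e-08, adjusted p = 0.405 with an estimated correlation), and included Itgax at 108 FPKM and Ctsk at 205 on HFD. Inflammatory genes rose in 18 of 19 (median 2.03, camera adjusted p = 2.87e-07, adjusted p = 0.405 with an estimated correlation), including the chemokine genes Ccl3 (2.69) and Ccl4 (2.12). Cell cycle genes rose in all 20 (median 1.92, camera adjusted p = 2.45e-09, adjusted p = 0.405 with an estimated correlation), including Ube2c (2.16). Matrix genes rose in 23 of 26 (median 1.68, camera adjusted p = 3.13e-08, adjusted p = 0.405 with an estimated correlation), including Tgfb1, the gene of a fibrosis-driving cytokine (1.77). Mast cell markers rose in 6 of 8 (median 2.12, camera adjusted p = 0.00419, adjusted p = 0.405 with an estimated correlation). T and NK cell markers rose in 7 of 9 (median 0.71, camera adjusted p = 0.0140, adjusted p = 0.405 with an estimated correlation). Antigen presentation genes rose in 11 of 14 and fell in 3 (median 1.29, camera adjusted p = 0.00733, adjusted p = 0.427 with an estimated correlation). Cholesterol synthesis genes rose in 16 of 20 and fell in 2 (median 0.89, camera adjusted p = 0.00206, adjusted p = 0.405 with an estimated correlation).

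Adipocyte identity genes fell in 19 of 20, with 1 higher (median -1.69, camera adjusted p = 1.34e-08, adjusted p = 0.405 with an estimated correlation). Genes of branched-chain amino acid breakdown fell in all 18 (median -1.41, camera adjusted p = 1.34e-08, adjusted p = 0.405 with an estimated correlation). Oxidative phosphorylation genes fell in 23 of 24 (median -0.66, camera adjusted p = 2.66e-08, adjusted p = 0.405 with an estimated correlation), with Sdha, shared with the citric acid cycle, among them (-0.83). Genes of triglyceride storage and lipolysis fell in 16 of 21 (median -1.09, camera adjusted p = 0.000116, adjusted p = 0.437 with an estimated correlation). They included the lipase genes Pnpla2 (-1.65) and Lipe (-1.85), the acyltransferase gene Gpam (-1.34) and Pck1, needed to make glycerol (-3.79). Lipogenesis genes fell in 8 of 17 (median -0.61, camera adjusted p = 0.00107, adjusted p = 0.405 with an estimated correlation), with Acaca (-1.93), Thrsp (-3.02) and Scd1 (-1.95). The genes of the HoxB cluster around Mir10a fell in 6 of 8 (median -0.78, camera adjusted p = 0.0192, adjusted p = 0.569 with an estimated correlation), with Hoxb4 at -0.66 (adjusted p = 0.00407). The mean log2 level of this list also fell in WT, from 2.26 to 1.61, against 2.18 to 1.38 in KO. On NCD it was highest in the ciliated libraries, at 2.79 in KO_NCD 2, 2.47 in WT_NCD 2 and 2.43 in WT_NCD 4. The other NCD libraries stood at 1.76 to 1.99. Klf11 (-0.11, adjusted p = 0.459) and Map3k7 (0.16, adjusted p = 0.139) showed no change past the threshold in KO, and Map3k7 passed it only without KO_NCD 4.

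In all, 8730 genes (60.9%) changed with diet in KO, 4967 higher and 3763 lower, and 2372 of them by at least 1. The balance of directions depended on the scaling, with 3989 higher and 4814 lower after quantile normalization and 3824 higher and 5188 lower after median centring. These scalings moved the median of all genes by -0.12 and -0.15 on the log2 scale in KO. Leaving out single libraries gave 7779 to 8656 genes, and all 53 named genes past the threshold stayed past it. Hoxb3 (-0.50, adjusted p = 0.0590) passed it only without KO_NCD 4 or KO_HFD 5. Diet effects in WT and KO correlated with r = 0.924 over all tested genes and a slope of 1.12 of KO on WT. Genes called in both numbered 3410 higher, where independent lists would share 1263 by chance, and 2898 lower, where they would share 954. In opposite directions, 12 genes were called. Of 33 lists, 17 were called with the preset correlation (9 higher, 8 lower), none with an estimated correlation, and 26 with fry.

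The comparison of KO with WT on NCD asked what loss of miR-10a changed in lean fat. It called 7 of 14340 genes, 6 higher and 1 lower. Nnt (NCBI gene 18115, chromosome 13, 119335527 to 119409257), which encodes the mitochondrial enzyme that makes NADPH from NADH, was at 6.81 ± 0.292 FPKM in WT and 16.8 ± 0.308 in KO (1.19, SE 0.05, adjusted p = 4.16e-06). AA465934 (613254, a long non-coding RNA, chromosome 11, 83291699 to 83294637) was at 1.23 ± 0.435 and 14.5 ± 3.77 (2.79, adjusted p = 0.000184). Xaf1 (327959, an interferon-induced promoter of cell death, chromosome 11, 72301461 to 72313733) was at 6.32 ± 0.323 and 20.9 ± 1.76 (1.58, adjusted p = 0.000405). Slfn8 (276950, a Schlafen gene of immune cells, chromosome 11, 83002125 to 83020810) was the lower gene, at 1.80 ± 0.197 in WT and 0.0914 ± 0.0205 in KO (-1.35, adjusted p = 0.000752). Entpd4 (67464, chromosome 14, 69337151 to 69366742) and Entpd4b (100862375, chromosome 14, 69555401 to 69584940), near-identical copies of a nucleotidase gene of the Golgi, had log2 fold changes of 0.83 and 0.83, and reads shared between the copies leave the change of each uncertain. Fndc8 (78919, chromosome 11, 82892145 to 82900737), named here after its values were seen, was at 0.181 ± 0.0577 and 1.2 ± 0.283 (0.89, adjusted p = 0.0331).

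Adipocyte, macrophage and matrix genes that moved with diet showed no genotype difference past the threshold on NCD. Lep was at 279 ± 93.4 in WT and 274 ± 99.0 in KO, and Adipoq at 2071 ± 193 and 2217 ± 306. Adgre1 was at 9.03 ± 2.03 and 6.94 ± 1.57, Ccl2 at 5.52 ± 0.863 and 3.72 ± 0.636, and Trem2 at 3.94 ± 0.0616 and 2.84 ± 0.771. Col1a1 was at 38.8 ± 3.19 and 36.1 ± 7.10 and Fasn at 541 ± 138 and 386 ± 111. Map3k7 (-0.06, adjusted p = 0.986) and Klf11 (-0.15, adjusted p = 0.983) did not pass either. Genes on lists moved by small amounts. Mast cell markers lay lower in KO with none of 8 past the threshold over all genes and 5 lower adjusted over the list alone (median -0.56, camera adjusted p = 7.67e-08, adjusted p = 0.281 with an estimated correlation). The protease gene Tpsb2 was at 11.2 ± 2.32 in WT and 5.11 ± 1.48 in KO, and Mcpt4 at 12.9 ± 1.83 and 6.92 ± 2.39. Tpsb2 passed the threshold only without KO_NCD 2. Immediate early genes lay lower, with none of 16 past and 4 lower adjusted over the list alone (median -0.31, camera adjusted p = 1.76e-08, adjusted p = 0.281 with an estimated correlation), such as Zfp36 (-0.28) and Dusp1 (-0.30). Interferon response genes lay higher (median 0.16, camera adjusted p = 2.41e-09, adjusted p = 0.491 with an estimated correlation), with Xaf1 the one member past the threshold and Ifi27l2a and Bst2 at 0.10 and 0.23. The interferon median was 0.04 without KO_NCD 3 and 0.30 without KO_NCD 4, and the mast cell median -0.91 without KO_NCD 2. Without the 3 ciliated libraries the interferon and immediate early calls were lost (adjusted p = 0.0740 and 0.0650).

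Further lists lay lower in KO on NCD. These were markers of resident-type macrophages (median -0.41, camera adjusted p = 0.000471, adjusted p = 0.491 with an estimated correlation) and of macrophages in general (median -0.25, camera adjusted p = 0.0144, adjusted p = 0.793 with an estimated correlation). They were also smooth muscle markers (median -0.43, camera adjusted p = 0.00465, adjusted p = 0.672 with an estimated correlation) and TGF-beta and BMP signalling genes (median -0.13, camera adjusted p = 0.0102, adjusted p = 0.491 with an estimated correlation). Cholesterol synthesis (median -0.22, camera adjusted p = 0.00465, adjusted p = 0.672 with an estimated correlation), lipogenesis (median -0.26, camera adjusted p = 0.0229, adjusted p = 0.672 with an estimated correlation) and lymph node stroma genes (median -0.84, camera adjusted p = 0.0376, adjusted p = 0.491 with an estimated correlation) followed. No member of these 7 lists passed over all genes, and adjusted over the list alone 1 member was lower in TGF-beta and BMP signalling, 1 in cholesterol synthesis and 1 in lymph node stroma. Single libraries moved these medians, that of resident-type macrophages to -0.23 without KO_NCD 3, of macrophages to -0.16 without WT_NCD 1 and of lipogenesis to -0.13 without KO_NCD 4. Without KO_NCD 2 cholesterol synthesis was at -0.11 and lymph node stroma at -0.50. Abundant members were Retnla (-0.49) and Folr2 (-0.50) of resident macrophages and Lyz2 (-0.33) and Ctss (-0.20) of macrophages. Others were Acta2 (-0.55) and Tagln (-0.63) of smooth muscle, Id3 (-0.13) and Tgfbr2 (-0.29) of TGF-beta signalling, and Insig1 (-0.26) of cholesterol synthesis. Lists of adipocyte identity (median 0.07, camera adjusted p = 0.0229, adjusted p = 0.793 with an estimated correlation) and branched-chain amino acid breakdown (median 0.03, camera adjusted p = 0.0144, adjusted p = 0.793 with an estimated correlation) were called higher. So were triglyceride storage (median 0.0041, camera adjusted p = 0.0276, adjusted p = 0.793 with an estimated correlation) and the cell cycle (median 0.01, camera adjusted p = 0.0376, adjusted p = 0.793 with an estimated correlation). None of their members passed over all genes or adjusted over the list alone. Each of these 4 medians turned negative without at least 1 of the libraries. Of these 4, after quantile normalization only the cell cycle list was still past the threshold, and triglyceride storage turned to lower (adjusted p = 0.942). After median centring all 4 lost their calls. With an estimated correlation none of the 14 called lists passed, and fry called none.

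Leaving out single libraries gave 6 to 15 genes on NCD, with 15 without KO_NCD 2 and 13 without KO_NCD 3, and the 6 named genes past the threshold stayed past it. Without the 3 ciliated libraries 4 genes were called, 2 of them among the 7, and Xaf1, Entpd4, Entpd4b and Slfn8 no longer passed (adjusted p = 0.0804 to 0.151) at log2 fold changes of 1.53, 0.82, 0.82 and -1.45. At an unadjusted p under 0.05, 731 of 14340 tested genes were counted, close to the share of 0.05 that would pass with no genotype difference.

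The comparison of KO with WT on HFD asked what loss of miR-10a changed in obese fat. Ctsk, Itgax and Fcgr1, which macrophages express, were higher in KO. Ctsk (NCBI gene 13038, chromosome 3, 95499210 to 95509387) was at 117 ± 4.70 FPKM in WT and 205 ± 29.0 in KO (0.80, SE 0.09, adjusted p = 0.00516). Itgax (16411, chromosome 7, 128129526 to 128150657) was at 57.7 ± 9.22 and 108 ± 24.7 (0.88, adjusted p = 0.0374). Fcgr1 (14129), an antibody receptor gene, was at 10.5 ± 1.51 and 15.4 ± 1.44 (0.52). Macrophage markers lay higher with 1 of 16 past the threshold over all genes and all 16 adjusted over the list alone (median 0.53, camera adjusted p = 1.70e-08, adjusted p = 0.364 with an estimated correlation). Among them were Lyz2 (0.69), Ctss (0.71) and Adgre1 (105 ± 19.5 and 171 ± 35.6). Lipid-associated macrophage markers did so with 2 of 16 past and 13 adjusted over the list alone (median 0.68, camera adjusted p = 6.01e-06, adjusted p = 0.364 with an estimated correlation). Trem2 was at 124 ± 25.4 and 203 ± 35.2 (0.71, adjusted p = 0.0684). Chosen after their values were seen, the scavenger receptor gene Stab1 (0.73) and Gdf3, a macrophage-made ligand of the adipocyte receptor encoded by Acvr1c (1.22), were also past the threshold. Not all immune lists lay higher. Camera did not call resident-type macrophage markers (median -0.06), inflammatory genes (0.17, and 0.03 without KO_HFD 8) or antigen presentation genes (0.11).

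Mast cell genes were higher in KO on HFD. Of 8 tested markers 6 passed (median 1.13, camera adjusted p = 2.79e-07, adjusted p = 0.364 with an estimated correlation, fry adjusted p = 0.00501). The tryptase gene Tpsb2 (17229, chromosome 17, 25366308 to 25368096) was at 15.6 ± 3.26 in WT and 38.9 ± 1.17 in KO (1.29, adjusted p = 0.0186). The chymase gene Cma1 (17228) was at 12.4 ± 2.80 and 29.9 ± 2.54 (1.23). Tpsab1 (100503895), annotated here as a transcribed pseudogene of the tryptase family, was at 0.334 ± 0.118 and 1.61 ± 0.131, and the IgE receptor gene Fcer1a (14125) at 1.12 ± 0.279 and 3.33 ± 0.740. The mean log2 level of the list lay between 3.42 and 3.49 in the KO libraries and between 2.24 and 2.64 in the WT libraries. B cell markers lay higher with 1 of 9 past (median 0.45, camera adjusted p = 0.0186, adjusted p = 0.487 with an estimated correlation), and the median was 0.24 without KO_HFD 5 and 0.26 without WT_HFD 4. The antibody genes Igkv3-10 (667924), Ighg3 (380795) and Igkv6-20 (108024) were higher in KO, at 0.136 ± 0.236 and 7.59 ± 4.62, 0.242 ± 0.0533 and 6.38 ± 3.51, and, listed at 0 in WT, 5.73 ± 4.22. Antibody genes share much of their sequence, so the level of each is uncertain.

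Adipocyte lists lay lower in KO on HFD, but part of this rested on KO_HFD 8, and on some lists the libraries of the genotypes overlapped. Rbp4 (19662, chromosome 19, 38116620 to 38125321), which encodes the retinol carrier that adipocytes secrete, was at 177 ± 33 in WT and 83.7 ± 28.2 in KO (-1.11, SE 0.21, adjusted p = 0.0476). It was the 1 of 20 adipocyte identity genes past the threshold, with 6 lower adjusted over the list alone (median -0.45, camera adjusted p = 1.70e-08, adjusted p = 0.364 with an estimated correlation). Adipoq (988 ± 147 and 604 ± 208, adjusted p = 0.0997) and Cfd (309 ± 138 and 141 ± 94.0) did not pass. Pmvk (68603), a cholesterol synthesis gene, was at 41.9 ± 0.867 and 25.6 ± 3.24 (-0.69, adjusted p = 0.0235). It was the 1 of 20 on its list past the threshold, with 9 lower adjusted over the list alone (median -0.26, camera adjusted p = 5.88e-06, adjusted p = 0.364 with an estimated correlation). Abundant members were Insig1 (-0.70) and Hmgcs1 (-0.43). Lists with no member past the threshold over all genes also lay lower. Triglyceride storage had 12 of 21 lower adjusted over the list alone (median -0.57, camera adjusted p = 2.70e-09, adjusted p = 0.364 with an estimated correlation), and branched-chain amino acid breakdown 15 of 18 (median -0.42, camera adjusted p = 1.69e-08, adjusted p = 0.364 with an estimated correlation). Fatty acid oxidation had 15 of 21 lower (median -0.34, camera adjusted p = 3.14e-08, adjusted p = 0.364 with an estimated correlation), and lipogenesis 8 of 17 lower and 1 higher (median -0.42, camera adjusted p = 5.88e-06, adjusted p = 0.364 with an estimated correlation). Oxidative phosphorylation had none past either way (median -0.25, camera adjusted p = 2.70e-09, adjusted p = 0.384 with an estimated correlation). By mean log2 level, WT_HFD 4 lay below KO_HFD 5 for adipocyte identity (5.75 against 5.82) and triglyceride storage (7.86 against 7.87). It also did for branched-chain amino acid breakdown (4.59 against 4.65) and fatty acid oxidation (5.73 against 5.75). The genotypes did not overlap for lipogenesis, oxidative phosphorylation and cholesterol synthesis. Without KO_HFD 8 the median of adipocyte identity genes went from -0.45 to -0.20, of triglyceride storage from -0.57 to -0.31, of branched-chain amino acid breakdown from -0.42 to -0.28 and of fatty acid oxidation from -0.34 to -0.24. Lipogenesis went from -0.42 to -0.34, oxidative phosphorylation from -0.25 to -0.21 and cholesterol synthesis from -0.26 to -0.30. The members included Fabp4, a fatty acid carrier gene (10517 ± 1509.8 and 7109 ± 1875), Lpl (-0.19), Aldh6a1 (-0.53), Hibadh (-0.37), Ech1 (-0.35), Scd1 (-0.86), Thrsp (-0.78), Atp5b (-0.34) and Cox4i1 (-0.28).

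Further lists moved with fewer calls. Endothelial (median -0.44, camera adjusted p = 5.18e-05, adjusted p = 0.486 with an estimated correlation) and thermogenic genes (median -0.35, camera adjusted p = 0.000637, adjusted p = 0.364 with an estimated correlation) lay lower. Without KO_HFD 8, which had a mean endothelial log2 level of 3.69 against 4.34 to 4.92 in the other HFD libraries, the endothelial median was -0.12 and the thermogenic median -0.23. Erythrocyte markers did as well, with 4 of 5 lower adjusted over the list alone (median -1.02, camera adjusted p = 0.000462, adjusted p = 0.364 with an estimated correlation). Interferon genes lay higher with Xaf1 past the threshold (median 0.28, camera adjusted p = 0.000812, adjusted p = 0.486 with an estimated correlation). Cell cycle (median 0.29, camera adjusted p = 2.52e-05, adjusted p = 0.486 with an estimated correlation) and immediate early genes (median 0.26, camera adjusted p = 0.00360, adjusted p = 0.407 with an estimated correlation) lay higher. Unfolded protein response (median 0.22, camera adjusted p = 0.0168, adjusted p = 0.486 with an estimated correlation), mesothelial (median 0.50, camera adjusted p = 0.0196, adjusted p = 0.618 with an estimated correlation) and matrix genes (median 0.34, camera adjusted p = 0.0331, adjusted p = 0.618 with an estimated correlation) did too, and no member of these lists passed over all genes. Without KO_HFD 8 the interferon median was 0.19 and the cell cycle median 0.19, and without WT_HFD 4 the cell cycle median was 0.46. Adjusted over the list alone, 2 interferon, 4 immediate early and 1 mesothelial gene were higher. Lep (1003 ± 160.1 in WT and 773 ± 226 in KO), Ccl2 (56.9 ± 28.1 and 48.5 ± 11.4), and Col1a1 (155 ± 54.8 and 220.4 ± 51.4) showed no difference past the threshold. Neither did Fasn (-0.61), Map3k7 (0.02, adjusted p = 0.940) and Klf11 (0.26, adjusted p = 0.228).

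Other genes with the highest and lowest values on HFD lay near Mir10a or in duplicated regions. Stac2 (217154, chromosome 11, 98036623 to 98053462), an adaptor of calcium channels, was at 4.45 ± 1.21 in WT and 14.5 ± 3.40 in KO (1.51, adjusted p = 0.00420). AA465934 (2.73) and Slfn8 (3.82 ± 0.359 and 0.616 ± 0.250, -1.59) differed as on NCD. Tmem254a, Tmem254b and Tmem254c (66039, 100039257 and 100039192, all on chromosome 14) had log2 fold changes of -1.32, -1.34 and -1.34 with adjusted p of 0.0322 to 0.0352, and as near-identical copies their single values are uncertain.

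In all, 115 genes differed between genotypes on HFD, 86 higher and 29 lower in KO, and 20 by at least 1. Quantile normalization gave 67 higher and 46 lower, and median centring 68 and 46. The count moved with single libraries, to 17 without WT_HFD 1, 19 without WT_HFD 2, 953 without WT_HFD 4, 24 without KO_HFD 3, 273 without KO_HFD 5 and 22 without KO_HFD 8. AA465934, Slfn8, Stac2 and Ctsk stayed past the threshold in each of these fits. The other 14 named genes past it, the mast cell genes included, lost their calls without at least 1 of WT_HFD 1, WT_HFD 2, KO_HFD 3, KO_HFD 5 and KO_HFD 8. Fitting only these 2 groups called 24 genes. Fitting without the 3 ciliated NCD libraries called 25, with the same fold changes and fewer libraries to estimate the spread. In that fit 12 of the 18 named genes, Rbp4, Itgax, Fcgr1, Cma1, Fcer1a, Pmvk, the 3 Tmem254 and the 3 antibody genes, no longer passed (adjusted p = 0.0522 to 0.110). Without WT_HFD 4, Trem2, Adgre1, Lyz2, Ctss, Col1a1, Scd1 and Aldh6a1 passed it. Of 33 lists, 20 were called with the preset correlation (10 higher, 10 lower), none with an estimated correlation, and 1 with fry.

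**Figure D2:**
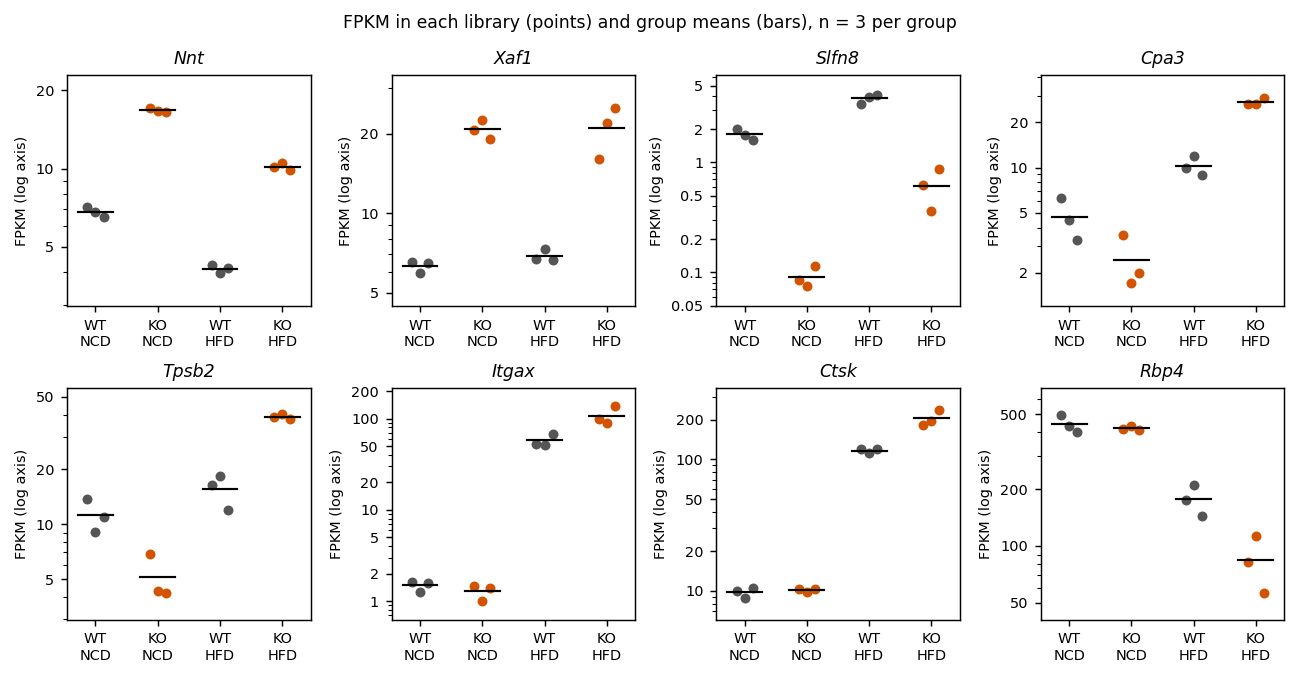
FPKM on a log axis of 8 genes in each of 12 libraries (points, WT in grey and KO in orange) with group means as bars, n = 3 per group. Nnt lies at a mean of 6.81 FPKM in WT and 16.8 in KO on NCD and at 4.12 and 10.2 on HFD, and Tpsb2 at 15.6 in WT and 38.9 in KO on HFD.

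Genotype effects on the 2 diets had a Pearson r of 0.0282 and a Spearman rank correlation of -0.122 over the 14340 tested genes. In genes with a mean of at least 5 FPKM these were -0.0247 and -0.201. With 7 genes called on NCD, noise can hide a shared effect, so these values do not show that the genotype effects differ between diets. Between the called genes, 5 were higher in KO on both diets, where 0.0360 would be shared by chance, and 1 was lower on both, where 0.00202 would be. The 6 were Nnt, AA465934, Entpd4, Entpd4b, Xaf1 and Slfn8, and no gene was called in opposite directions. On HFD, Nnt was at 4.12 ± 0.137 in WT and 10.2 ± 0.351 in KO (1.13, adjusted p = 7.28e-06) and Xaf1 at 6.88 ± 0.351 and 21 ± 4.55 (1.46). In a test of the genotype effect averaged over the diets, added after the data were seen, 25 genes passed. Of these, 12 lay within 25 Mb of Mir10a on chromosome 11, a window that held 681 of the 14340 tested genes (4.75%), and Fisher's exact test gave an odds ratio of 18.8 (p = 3.52e-10). The 12 were AA465934, Xaf1, Slfn8, Mrps23, Slc43a2, Fndc8, Tlcd2, Arl5c, Dgke, AI450353, Stac2 and Unc45b. Mrps23 (a gene of the mitochondrial ribosome) was at 23.2 ± 1.09 in WT and 17.6 ± 0.970 in KO on NCD and at 24.2 ± 0.562 and 19.1 ± 0.654 on HFD. Slc43a2 (an amino acid transporter gene) was at 4.78 ± 0.260 and 8.13 ± 1.63, and at 11.3 ± 1.52 and 22.2 ± 1.49. By Fisher's exact test the window held 4 of the 7 genes called on NCD (odds ratio 26.9, p = 0.000157) and 19 of the 115 called on HFD (odds ratio 4.05, p = 1.86e-06), against 4.75% of tested genes.

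**Figure D3:**
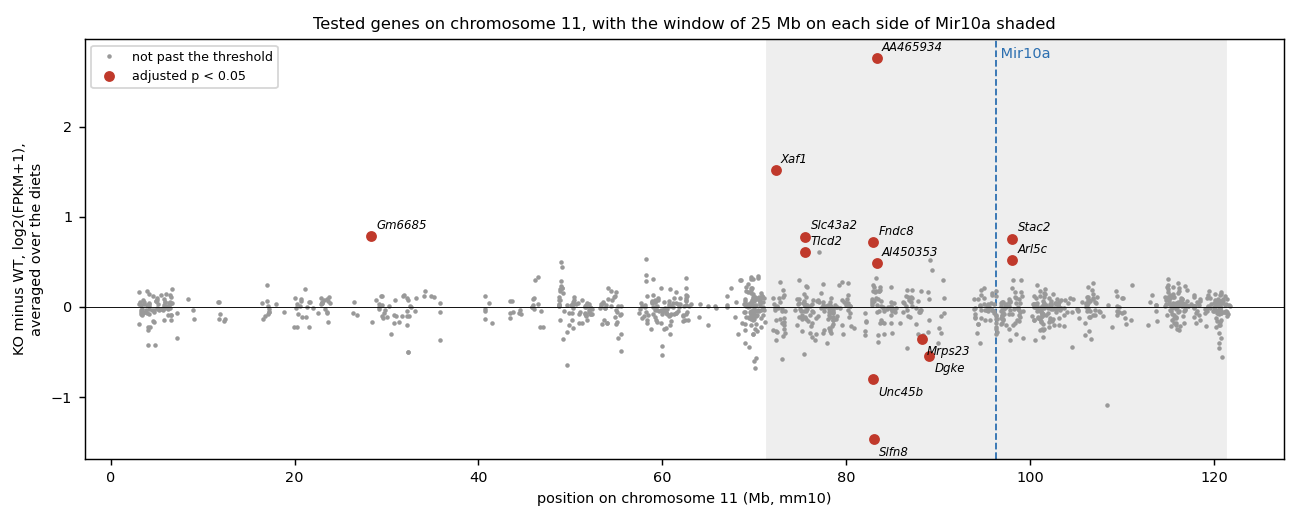
Difference between KO and WT in log2(FPKM + 1), averaged over the diets, of each tested gene against its position on chromosome 11 in Mb (mm10), n = 6 libraries per genotype. Red points mark genes with an adjusted p under 0.05, the shaded band is the window of 25 Mb on each side of Mir10a, and 12 of the 13 marked genes lie in it.

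Genes with a site for the miR-10a seed were compared with genes without one, since loss of a microRNA releases the mRNAs it targets. In 1866 genes the longest 3' UTR held an 8mer or 7mer-m8 site. Their median change lay -0.0035 from that of the 10616 genes without a site on NCD (camera p = 0.600, p = 0.803 with an estimated correlation) and 0.03 from it on HFD (camera p = 0.161, p = 0.511 with an estimated correlation). Among 100 control 7-base sequences these differences stood at percentiles 68 and 99. Genes with a site had longer 3' UTRs, with a median of 2508 against 1136 bases. A list of reported miR-10a targets, including Map3k7 and Klf11, moved by -0.09 on NCD (camera adjusted p = 0.334, adjusted p = 0.699 with an estimated correlation) and by 0.02 on HFD (camera adjusted p = 0.872, adjusted p = 0.892 with an estimated correlation). With limma, 0 of its 18 tested members passed on either diet, over all genes or adjusted over the list alone.

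The interaction asked whether the diet effect differed between genotypes. Mast cell protease genes led it. Tpsb2 differed by 2.30 (SE 0.27, adjusted p = 0.0248), rising from 5.11 ± 1.48 to 38.9 ± 1.17 FPKM in KO and standing at 11.2 ± 2.32 and 15.6 ± 3.26 in WT. Mcpt4 (17227, another chymase gene) differed by 2.08 (adjusted p = 0.0328), Cpa3 (12873, the mast cell carboxypeptidase gene) by 2.06 and Cma1 by 1.94. Stac2 differed by 1.49 (adjusted p = 0.0449), at 1.16 ± 0.0519 and 14.5 ± 3.40 in KO against 1.15 ± 0.216 and 4.45 ± 1.21 in WT. Wfdc21 (66107, a small secreted protein gene at chromosome 11, 83746940 to 83752646) was the 1 gene lower (difference -1.80), at 61.0 ± 0.140 and 57.9 ± 11.5 in KO against 32.5 ± 7.59 and 107 ± 8.02 in WT. Of 8 mast cell markers 6 passed (median 1.66, camera adjusted p = 2.72e-09, adjusted p = 0.381 with an estimated correlation, fry adjusted p = 0.00225). Macrophage markers had none of 16 past over all genes and 15 adjusted over the list alone (median 0.79, camera adjusted p = 6.56e-09, adjusted p = 0.425 with an estimated correlation), with Lyz2 at 1.01, Ctss at 0.91, Adgre1 at 1.03 and Trem2 at 1.09. Immediate early genes had none past and 12 of 16 adjusted over the list alone (median 0.67, camera adjusted p = 4.73e-07, adjusted p = 0.425 with an estimated correlation), with Dusp1 at 0.85, past the threshold only without WT_HFD 4. Adipocyte identity genes had none past and 3 lower adjusted over the list alone (median -0.49, camera adjusted p = 2.72e-09, adjusted p = 0.425 with an estimated correlation), with Adipoq at -0.86 and Fabp4 at -0.64. Lep (-0.38), Ccl2 (0.32), Col1a1 (0.66), Fasn (-0.11), Map3k7 (0.08), Klf11 (0.42) and Hoxb4 (-0.20) did not pass.

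The interaction called 39 genes, 38 higher and 1 lower, and quantile normalization called 4 (3 higher, 1 lower) and median centring 13 (11 higher, 2 lower). These scalings moved the median of all genes by -0.10 and -0.11. No gene was called without WT_NCD 1, WT_NCD 4, KO_NCD 3, KO_NCD 4 or WT_HFD 1, with limma in each case. Without WT_NCD 2 it was 15 genes, without KO_NCD 2 168, without WT_HFD 2 1, without KO_HFD 3 2, without KO_HFD 5 4, without KO_HFD 8 2 and without WT_HFD 4 33. None of the 6 named genes past the threshold stayed past it in all 12 of these fits. Without the 3 ciliated libraries, which leaves 1 WT library on NCD, 17 genes were called, 9 of them among the 39. Cma1 (2.31, adjusted p = 0.0627) and Stac2 (1.49, adjusted p = 0.191) then no longer passed, nor did the lists of endothelial, lipogenesis, cholesterol synthesis, cell cycle and unfolded protein response genes (adjusted p = 0.0717 to 0.133). Of 33 lists, 19 were called with the preset correlation (9 higher, 10 lower), none with an estimated correlation, and 2 with fry.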

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

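The tests of the chromosome 11 window, of single libraries, of cell types against each other, of ciliated, epididymal and spermatid transcripts were chosen after the results were seen. So was the check of miR-10a target release in genes near Mir10a that were lower in KO.

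Mast cell genes drew attention because the effect of the diet differed between genotypes in a test of that difference. The interaction called 39 genes. Tpsb2 differed by 2.30 on the log2 scale between KO and WT, Mcpt4 by 2.08, Cpa3 by 2.06 and Cma1 by 1.94, all 4 of them proteases stored in mast cell granules. The calcium channel adaptor gene Stac2 differed by 1.49 and Wfdc21 by -1.80. The median difference over a list was 1.66 for mast cell markers, 0.79 for macrophage markers, 0.78 for lipid-associated macrophage markers and 0.65 for B cell markers. It was 0.43 for adipose progenitors, -0.31 for endothelial, 1.02 for mesothelial and -1.10 for erythrocyte markers. For metabolic genes it was -0.49 for adipocyte identity, -0.11 for lipogenesis, -0.52 for triglyceride storage, -0.036 for cholesterol synthesis, -0.33 for thermogenic genes, -0.32 for fatty acid oxidation, -0.19 for oxidative phosphorylation and -0.43 for branched-chain amino acid breakdown. For responses it was 0.28 for the cell cycle, 0.29 for the unfolded protein response and 0.67 for immediate early genes. These lists passed camera only with the preset correlation, with estimated adjusted p of 0.381 or more, and fry called the mast cell list (adjusted p = 0.00225) and the immediate early list (adjusted p = 0.0209). Of 100 splits of genotype within each diet, the real one among them, 13 gave at least 39 genes, the real one included. Chance cannot be excluded, and the highest other split gave 548. Of those 13, 11 set WT_NCD 2, WT_NCD 4 and KO_NCD 2 against the other NCD libraries, which points to the ciliated transcripts as a structure of the samples. Without such splits the highest other count was 107.

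Many genes that differed between genotypes on both diets lay near Mir10a on chromosome 11. Of 25 such genes 12 lay within 25 Mb of it (odds ratio 18.8, Fisher's exact p = 3.52e-10). Strain DNA carried along with the targeted locus would give this. It would not cover Nnt on chromosome 13, nor groups of neighbouring genes on chromosome 14. These were Entpd4, Entpd4b and Gm16867 (69337151 to 69584940) and Tmem254a, Tmem254b, Tmem254c and Gm9780 (25923298 to 26207025). DNA differences away from Mir10a were not tested. The genotype comparisons, those of mast cell and macrophage genes included, cannot separate such differences from loss of miR-10a. Release of miR-10a targets is argued against for 4 of the 12, Slfn8, Mrps23, Dgke and Unc45b, because these were lower in KO. Their direction was known when this check was chosen, so it restates their values and was not an independent test. Among the 8 higher genes of the region, such as AA465934 and Xaf1, the site share was 0% of the 6 genes of the region with a 3' UTR against 14.9% elsewhere (Fisher's exact p = 0.601), too few to tell. Among genes short of the threshold, 7 of 658 in the window and 78 of 13559 elsewhere moved the same way on both diets with p under 0.05 (odds ratio 1.86, Fisher's exact p = 0.116), which leaves open whether the region as a whole is shifted. The averaged test itself gave 25 genes, and 14 of 100 splits gave as many, the real one included, with 548 in the highest other split. Its count therefore cannot be told from chance. Of those 14, 11 set the ciliated libraries apart, and without such splits the highest other count was 107.

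Macrophage markers lay higher and adipocyte genes lower in KO than in WT on HFD. Scaling by a few abundant genes is argued against, because the macrophage median of 0.53 stayed at 0.54 after quantile normalization and 0.49 after median centring, with the adipocyte median at -0.44 after quantile normalization. Without the most extreme library, KO_HFD 8, the macrophage median was 0.47, so that library is not its only source. The adipocyte median of -0.45 went to -0.20, so for Adipoq and its list 1 library may carry much of the difference. On the mean log2 level of that list WT_HFD 4 (5.75) also lay below KO_HFD 5 (5.82), so the genotypes overlapped. Over all 6 libraries left out in turn the macrophage median ranged from 0.46 to 0.69 and the adipocyte median from -0.64 to -0.20. A lower share of adipocytes would raise all other cell types alike. Mast cell markers moved away from endothelial markers by 1.41 (SE 0.29, no overlap between libraries), which it does not allow as the whole cause, while macrophage against endothelial markers moved by 1.00 (SE 0.50) with overlap. Without KO_HFD 8 these distances were 1.13 and 0.61. An effect of the genotype on macrophages stays open and untested beyond the comparison itself.

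Ciliated-epithelium transcripts marked WT_NCD 2, WT_NCD 4 and KO_NCD 2. Of 28 genes listed for cilia and duct epithelium 20 reached 1 FPKM, and 100% of these had the same 3 libraries highest. These libraries were singled out after genes of ciliated epithelium had been noticed in them, and genes of a cell type rise together. The 100% therefore shows that the listed genes go with the noticed ones, and it has no chance share to be set against. The genes noticed first are not on that list. In these libraries Mmp7 stood at 62.7, 32.9 and 62.9 FPKM, Ccdc153 at 28.5, 22.5 and 44.3 and Foxj1 at 17.4, 11.1 and 25.3. Efferent duct or another ciliated epithelium taken with the fat pad would give such levels, and was not tested apart from these transcripts. Of the 20 listed genes, 6 also reached 1 FPKM in another library. On the mean log2 level of the list, the lowest KO library on NCD lay -1.39 from the highest WT library. The levels ran from 0.64 to 2.26 in KO and from 0.49 to 2.03 in WT, so the genotypes overlapped. This overlap argues against the genotype as the whole source. With 3 libraries per group a smaller effect cannot be excluded. Epididymal duct tissue is argued against too, since the highest of 8 listed duct genes was at 0.568 FPKM in these libraries. Testis tissue or sperm cells stay open. Of 5 listed spermatid genes 40% reached 1 FPKM with these 3 libraries highest on NCD, with Prm2 at 1.19, 5.22 and 2.60 FPKM against 0.236 or less in the other NCD libraries, though WT_HFD 1 had 2.18.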

How the results depend on the processing

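Median centring, leaving out the 3 ciliated libraries and leaving out genes within 25 Mb of Mir10a were chosen after seeing the data, and the other alternatives before. Counts of changed genes were 7279 and 8730 for the diet in WT and KO, 7 and 115 for the genotype on NCD and HFD and 39 for the interaction. With a log2 change of at least 1 they were 1617, 2372, 4, 20 and 17, since that threshold is stricter. With a stricter filter, which tests fewer genes, the diet counts were 4696 and 5766 and the HFD genotype count was 232, of which 82 were among the 115. Without a filter the NCD genotype count was 14 and the interaction 24, and the cause was not tested. With only the 2 groups compared, which leaves fewer samples, the genotype counts were 11 and 24, with 6 and 19 shared. Without the 3 ciliated libraries, which leaves 1 WT library on NCD that is assumed to vary like the other groups, the diet count in WT was 3878, the genotype counts were 4 and 25 (2 and 24 shared) and the interaction 17 (9 shared). Without genes near Mir10a the genotype counts were 3 and 76, from fewer genes tested. Quantile normalization gave 4 and median centring 13 genes for the interaction, and the cause was not tested. Higher and lower genes for the diet in KO went from 4967 and 3763 to 3989 and 4814 with quantile normalization and 3824 and 5188 with median centring. For the genotype on HFD they went from 86 and 29 to 67 and 46 and to 68 and 46, and for the interaction from 38 and 1 to 3 and 1 and to 11 and 2.

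Leaving out single libraries gave 5849 to 7166 and 7779 to 8656 genes for the diet in WT and KO. It gave 6 to 15 for the genotype on NCD, with the highest without KO_NCD 2 and 13 without KO_NCD 3. On HFD it gave 17 (without WT_HFD 1) to 953 (without WT_HFD 4), with 19 without WT_HFD 2, 24 without KO_HFD 3, 273 without KO_HFD 5 and 22 without KO_HFD 8. For the interaction it gave 0 (without WT_NCD 1, WT_NCD 4, KO_NCD 3, KO_NCD 4 or WT_HFD 1) to 168 (without KO_NCD 2), with 15 without WT_NCD 2, 1 without WT_HFD 2, 2 without KO_HFD 3, 4 without KO_HFD 5 and 2 without KO_HFD 8. At an unadjusted p under 0.05 the interaction had 2649 genes with all libraries.

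Gene lists called numbered 16 and 17 for the diet in WT and KO, 14 and 20 for the genotype on NCD and HFD and 19 for the interaction. With an estimated correlation camera called 0, 0, 0, 0 and 0, and fry 22, 26, 0, 1 and 2, the 1 on HFD being mast cell markers. Of 228 results for named genes, 3524 values under the alternatives were compared. Of these, 3325 kept the side of the threshold, 179 lost the call and 20 gained it. Direction was compared only where the main fit or the alternative called the gene, and 0 of those values changed direction. For genes called in neither fit, a change of sign was not counted. Seed-site differences and the correlations between comparisons kept their direction and side, except that the correlation of genotype effects went from 0.0282 to -0.0247 in genes of at least 5 FPKM. No paired analysis was possible because the numbers in the column headers do not match the replicate numbers of the labels and differ between groups. The planned count-based alternatives were not run, as the table holds no counts. Depth is unknown, so its limit on low genes such as Fndc8 and Slfn8 could not be given.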

Other observations

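The test of Nnt and the ciliated libraries in the genotype splits were chosen after the results were seen. Clock genes and red cell genes moved with diet in both genotypes, and the genes named here were chosen after their values were seen. Of 16 circadian clock genes 11 fell and 4 rose in WT (median -1.24, camera adjusted p = 0.0132, adjusted p = 0.317 with an estimated correlation). In KO 10 fell and 3 rose (median -0.83, camera adjusted p = 0.0363, adjusted p = 0.405 with an estimated correlation), and the call was lost after quantile normalization (adjusted p = 0.0913) and median centring (adjusted p = 0.107). Genes that fell included Dbp from 64.1 ± 9.53 to 9.86 ± 5.26 FPKM in WT and from 51.0 ± 21.2 to 14.7 ± 5.06 in KO, Nr1d1 (log2 fold change -1.99 and -1.62), Per3 (-2.00 and -1.59) and Tef (-1.73 and -1.40). Genes that rose included Arntl from 1.54 ± 0.190 to 6.09 ± 1.40 in WT and from 2.04 ± 0.843 to 6.09 ± 0.987 in KO, and Nfil3 (1.51 and 0.99). The labels give no time of day for the dissections. Erythrocyte markers fell in 4 of 5 in WT (median -0.87, camera adjusted p = 0.111, adjusted p = 0.670 with an estimated correlation) and in all 5 in KO (median -1.96, camera adjusted p = 0.00776, adjusted p = 0.435 with an estimated correlation), where Hbb-bs went from 622 ± 178 to 158 ± 39.6 FPKM.

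Single genes on HFD, chosen after their values were seen, moved without a list test. Tph2, which rose with diet in WT to 48.5 ± 3.48 FPKM, was at 29.9 ± 4.73 in KO on HFD (-0.69, adjusted p = 0.0235), while Htr2b, a serotonin receptor gene, was at 1.71 ± 0.118 in WT and 4.32 ± 1.17 in KO (0.95, adjusted p = 0.0176). Klb, which encodes the co-receptor for the hormone FGF21 in adipocytes, was at 8.77 ± 0.907 in WT and 4.25 ± 0.751 in KO (-0.90, adjusted p = 0.0316). The 2 mitochondrial ribosomal RNA genes were lower in KO on HFD, mt-Rnr1 at 389 ± 34.5 and 233 ± 14.6 and mt-Rnr2 at 406 ± 34.7 and 235 ± 38.2 FPKM. HFD libraries of KO had 7.52% to 9.83% of summed FPKM on mitochondrially encoded transcripts against 9.24% to 13.1% in WT. Within the HoxB cluster, Hoxb9 was at 5.73, 3.51 and 6.17 FPKM in the 3 ciliated NCD libraries and at 0.892 to 1.17 in the other NCD libraries, so diet effects on this cluster mix with the ciliated transcripts.

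Nnt was higher in KO on both diets. C57BL/6J mice are known to carry a deletion within Nnt that other C57BL/6 mice lack, so a candidate explanation is that WT mice carried it and KO mice did not, which stays open. The lowest KO library lay at 16.5 FPKM against 7.10 in the highest WT library on NCD, and at 9.85 against 4.25 on HFD. The smaller of these gaps was 1.05 on the log2 scale, but that restates the higher level in KO and favours no cause over another. A gene-level FPKM does not show which exons were read, so the deletion itself was not seen.

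Release of mRNAs with miR-10a seed sites was tested as a direct effect of the knockout. The median difference between 1866 genes with and 10616 without a site was -0.0035 on NCD and 0.0275 on HFD, and camera called neither, so an effect may be present or absent. For 8mer sites alone, in 280 genes, it was -0.0087 and 0.0439, and camera again called neither. The value on HFD stood at percentile 99 among 100 control sequences. Genes with a site had longer 3' UTRs (median 2508 against 1136 bases). The controls were also scored by the genes that carry them, so the percentile may already allow for part of a length effect. The 3' UTR lengths of those control genes were not compared, so length stays open. The 8mer value on HFD lay above the highest control (0.0275), with camera p = 0.0546 and p = 0.426 with an estimated correlation. On NCD the 8mer value stood at percentile 12. The same controls served for all sites and 8mer genes were fewer, so these 8mer placings are not like for like.

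For the diet effects and the genotype effects within a diet, 6 libraries make 10 splits into 3 and 3, and 10 splits cannot give a share under 0.1. The real split was the 1 with the highest count for the diet in WT (7279 genes, highest other 0), the 1 for the diet in KO (8730, highest other 0) and the 1 for the genotype on HFD (115, highest other 0). For the diet, every other split mixes NCD and HFD libraries within its groups. That widens the spread of genes that moved with diet, so the counts of 0 there say little about chance. On NCD, 2 of 10 splits gave at least the real 7 genes, and the other one, WT_NCD 2, WT_NCD 4 and KO_NCD 2 against the rest, gave 692, which points to the ciliated transcripts as the main structure among the NCD libraries.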
